A study of soil metagenome with 18 samples.

How the data were processed

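Total RNA was measured by metatranscriptome sequencing in a bacterial consortium enriched from soil. It was grown in minimal salts medium with ammonium on either thiabendazole (TBZ) or succinate (SUC) as carbon source, at 15 µg/ml of carbon each. Thiabendazole, a benzimidazole fungicide and anthelmintic, was given at 25 µg/ml (125 µM). Succinate, an intermediate of the TCA cycle, was given at 37 µg/ml (314 µM). Cultures were sampled 57, 73 and 109 h after inoculation, with 3 libraries (a, b and c) in each of the 6 groups, 18 libraries in all. The RNA was depleted of ribosomal RNA and made into libraries with a stranded kit (KAPA). The labels do not say that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

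The authors deposited raw counts per feature, with no normalization. Their processing notes name CASAVA, Trimmomatic 0.36, STAR and HTSeq 0.9.1 without giving their roles, and do not state the annotation, the strand setting or how reads shared between genes were handled. Genes with near-identical copies in related genomes, such as the Sphingomonas, Novosphingobium and Sphingopyxis bins, are therefore uncertain, as are overlapping and antisense genes. The table holds 95542 features. Of these, 317 stand for contigs without annotated features and were kept out of every test. The other 95225 are annotated features of 39 metagenome bins, here called genomes and named as in the feature IDs, or of contigs outside the bins. The IDs of 57 features end in aS, bS or cS, whose meaning the table does not give. The files do not pair IDs with gene names or products, so genes are given by ID and their functions are not described. The gene list tests (camera, with an estimated correlation and with fry as alternatives) and the alternative without residual ribosomal RNA features need names and were not run.

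Genes were tested with edgeR 4.0.16 in R 4.3.3, by robust quasi-likelihood fits of all 18 libraries with a mean for each of the 6 groups (12 residual degrees of freedom) and TMM factors. The low-count filter filterByExpr left 23006 genes, 21087 of them in genomes and 1919 outside. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes within a comparison, and a gene passed at an adjusted p under 0.05. Thiabendazole was compared with succinate at each time, neighbouring times were compared within each carbon source, and interaction contrasts tested whether the carbon source difference changed between neighbouring times. Log2 fold changes carry standard errors derived from the F statistic. Normalised read counts (CPM) use the TMM-scaled library size. By a fixed rule, the named genes of a carbon source comparison were the top 2 in each direction by mean CPM in the higher group. They were taken from genes past the test with an absolute log2 fold change of at least 1 and no overlap between the CPM of the 3 and 3 libraries.

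A metatranscriptome count mixes how much RNA an organism contributes with how strongly it transcribes a gene. The share of each genome in a library's annotated counts was therefore tested apart, by the same edgeR model on genome sums with annotated counts as library size. The 19 genomes that reached a mean share of 0.1% in a group were adjusted together with the sum outside the bins. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1 and was not used for calls. Shares in single libraries have 95% Clopper-Pearson intervals, the widest of which spanned 0.135 percentage points for the shares outside the bins and on contigs without annotated features. A count of 0 allows a share of up to 3 counts of the library's annotated total. Intervals and floors cover counting error only.

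The design, the tests, the naming rule and most alternatives were fixed before the data were examined. These alternatives were DESeq2's size factors (RLE) in the edgeR fit, library totals only, scaling within each genome, no filter and a fixed filter (10 counts in 3 libraries). Also fixed were DESeq2 1.42.0, limma-voom (limma 3.58.1), fits of the compared groups only, replicate blocks, a test against a fold of 1.5, and each library left out in turn. For genome shares they also included leaving out the 20 most abundant features. Alternatives chosen after seeing the data were genes of bins only, shares of binned counts, and fits without the 5 libraries with over 75% of annotated counts outside the bins. The tests of Sphingomonas genes scaled within the genome were also added then. Scaling within genomes used the 9 genomes with at least 200 tested genes and 300 counts in every library (18765 genes).

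The fits were tested on simulated data with 200 changed genes. In the fits of 23006 genes, all other genes had 1 mean level over all libraries, so no genome shifted as a whole. Far fewer genes were called than in the data, so the rates need not carry over to the comparisons. In the simulation of the 57 h comparison, 12.1% of the genes changed 4-fold and 50% of those changed 16-fold were recovered. Of its 42 calls, 1 was false (2.38%). At 73 h the recovery was 1.52% and 43.9%, with 1 of 31 calls false (3.23%). At 109 h it was 4.55% and 65.2%, with 1 of 47 calls false (2.13%). Scaling within genomes at 73 h gave 2 false of 15 calls (13.3%) and a median log2 fold change of 6.63 for genes raised 2-fold. Calls of that fit at 73 h are therefore given only among the alternatives.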

Results

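RNA counts of a thiabendazole-degrading consortium were compared between growth on thiabendazole and on succinate. The series asks what a Sphingomonas member does in this consortium and how it interacts with the others. Groups are written by carbon source and time, as TBZ_57 for thiabendazole at 57 h. Total counts of libraries a, b and c were 2820296, 7003423 and 6503542 in TBZ_57, and 7051872, 3862498 and 5241419 in SUC_57. At 73 h they were 3981025, 3778146 and 3883638 in TBZ_73, and 1909457, 1994664 and 12320911 in SUC_73. At 109 h they were 2976283, 11675884 and 3341840 in TBZ_109, and 4170315, 2997174 and 3289971 in SUC_109. The genomes held between 73458 and 4729652 of these counts per library.

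Features outside the genomes took a large and uneven part of the annotated counts. Their mean share was 45.5% ± 29.3 (SD, n = 3) in TBZ_57, 31.1% ± 4.82 in TBZ_73 and 39.5% ± 41.9 in TBZ_109. On succinate it was 14.3% ± 7.09 in SUC_57, 93.6% ± 3.88 in SUC_73 and 6.36% ± 2.93 in SUC_109 (n = 3 each). The share was over 75% in 5 libraries, which were TBZ_57 a (78.4%), SUC_73 a (89.2%), SUC_73 b (94.9%), SUC_73 c (96.7%) and TBZ_109 b (87.6%). In the 3 SUC_73 libraries the genomes held only 152618, 73458 and 181694 counts, and every comparison of genomes or their genes with SUC_73 rests on these. The 57 features with suffixed IDs took from 0.799% (SUC_73 a) to 67.7% (SUC_73 c) of annotated counts. Whether these or the features outside the bins are residual ribosomal RNA was not tested, since the files give no names, so shares are of all annotated RNA and not of mRNA alone. Pearson's r of log CPM across genes, which are not independent replicates, lay between 0.318 and 0.517 within SUC_73 and between 0.893 and 0.939 within SUC_109. It was also low within TBZ_57, at 0.340 to 0.727, and within TBZ_109, at 0.615 to 0.872. Within SUC_57 it was 0.813 to 0.864, and within TBZ_73 0.884 to 0.921.

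**Figure D1:**
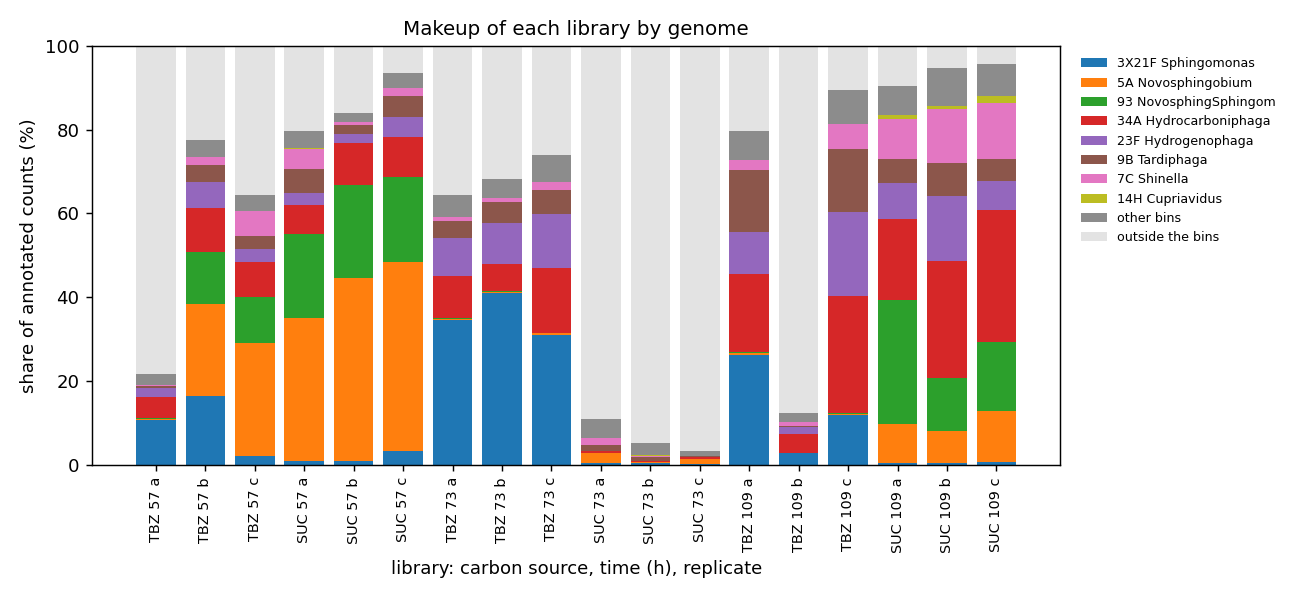
Make-up of each of the 18 libraries, with the share of annotated counts (%) of the named genomes, the other genomes and the features outside the bins as stacked bars. Features outside the bins took 89.2 to 96.7% of the SUC_73 libraries, 78.4% of TBZ_57 a and 87.6% of TBZ_109 b.

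At 57 h, most genes higher on thiabendazole than on succinate were of Bin_3X21F_Sphingomonas, and most lower ones of Bin_5A_Novosphingobium. Of the 2654 tested Sphingomonas genes, 1738 were higher, with a median log2 fold change of 4.01 over all its tested genes. They made up 82.2% of the genes that were higher. Scaled within the genome, 310 were higher and 105 lower (edgeR). Of the 2438 tested Novosphingobium genes, 137 were lower, 77.8% of the genes that were lower. Bin_23F_Hydrogenophaga had 37 higher genes of 2805, and the features outside the bins had 326 higher and 21 lower of 1919.

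The unbinned gene unbinned_06397 stood at 12081 ± 9962 CPM on thiabendazole against 185 ± 233 on succinate (SD, n = 3 each), a log2 fold change of 6.03 (SE 1.54, edgeR adjusted p = 0.00455). Bin_3X21F_Sphingomonas_02666 stood at 3504 ± 2685 against 123 ± 123 CPM, a log2 fold change of 4.83 (SE 1.28, edgeR adjusted p = 0.0066). Of the genes lower on thiabendazole, Bin_54_Commonadaceae_00141 stood at 16.7 ± 14.1 against 131 ± 122 CPM, a log2 fold change of -2.93 (SE 0.986, edgeR adjusted p = 0.0465). Bin_5A_Novosphingobium_00864 stood at 11.5 ± 10.96 against 90.4 ± 61.8 CPM, a log2 fold change of -2.91 (SE 0.983, edgeR adjusted p = 0.0477). In these genes the CPM of all 3 thiabendazole libraries lay on one side of all 3 succinate libraries, as the naming rule required. The calls of these Commonadaceae and Novosphingobium genes were lost under 10 of 17 and 10 of 18 alternatives (adjusted p from 0.0078 to 0.342 and from 0.0104 to 0.573). That of unbinned_06397 was lost under 1 of 16, without SUC_57 a (edgeR adjusted p = 0.05), and leaving out 1 library gave a log2 fold change of 5.28 to 8.20. That of Sphingomonas_02666 was lost under 4 of 18, among them scaling within the genome, where the log2 fold change was 1.24.

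In all, 2291 genes passed the edgeR test at 57 h, 2115 higher and 176 lower on thiabendazole. The CPM of the 2 groups did not overlap for 6393 genes (27.8%, against 10% by chance). With library totals only the count was 1384, with 10 lower, so the lower calls in Novosphingobium and other genomes depended on the scaling. They also depended on single libraries, with 19, 11 and 770 lower genes without TBZ_57 a, b and c. Without TBZ_57 b the count was 1418. As a share of annotated counts, Sphingomonas took 9.67% ± 7.18 on thiabendazole and 1.58% ± 1.39 on succinate (n = 3 each), a log2 difference of 2.61 (SE 1.08) that did not pass (edgeR adjusted p = 0.272). TBZ_57 c, with 2.04%, lay below SUC_57 c, with 3.19%. Of binned counts alone the difference was 3.80 and passed (edgeR adjusted p = 0.00554), although the same 2 libraries overlapped there, at 3.17% and 3.41%. Novosphingobium took 16.4% ± 14.3 and 41.0% ± 6.02, and this difference did not pass (log2 -1.32, edgeR adjusted p = 0.822).

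At 73 h, Sphingomonas was the largest genome on thiabendazole, at 35.5% ± 5.05 of annotated counts against 0.238% ± 0.195 on succinate (n = 3 each), a log2 difference of 7.22 (SE 1.33, edgeR adjusted p = 1.24e-05). Its 3.75 log2 difference in binned counts passed too (edgeR adjusted p = 0.00078). Bin_23F_Hydrogenophaga took 10.6% ± 2.06 against 0.0581% ± 0.0374, a log2 difference of 7.51 (SE 1.28, edgeR adjusted p = 3.81e-06), and 3.52 in binned counts (edgeR adjusted p = 0.00104). Of the genes tested in each genome, 2055 of Sphingomonas and 1656 of this Hydrogenophaga were higher on thiabendazole. In Novosphingobium 1035 genes were lower and 3 higher. Its share of annotated counts, 0.385% ± 0.0168 against 1.37% ± 1.12, did not pass (log2 -1.83, edgeR adjusted p = 0.145), but that of binned counts did (log2 -5.35, edgeR adjusted p = 6.54e-05). Bin_34A_Hydrocarboniphaga took 10.6% ± 4.47 against 0.389% ± 0.118 of annotated counts (log2 4.77, edgeR adjusted p = 0.000328), but its difference in binned counts, 1.07, did not pass (edgeR adjusted p = 0.161).

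Bin_3X21F_Sphingomonas_00845bS reached 51938 ± 11383 CPM on thiabendazole at 73 h against 592 ± 1015 on succinate, a log2 fold change of 6.46 (SE 1.80, edgeR adjusted p = 0.00554). The succinate value rests on 1, 4 and 495 counts in SUC_73 a, b and c, so the size of the fold was set by SUC_73 c. It was 13.45 without that library and 6.02 without SUC_73 a, and the call was kept in each fit that left out 1 library (edgeR adjusted p from 0.000199 to 0.0329). The call was lost with scaling within the genome (log2 1.25, edgeR adjusted p = 0.509). The gene unbinned_06397 reached 32587 ± 11538 against 20.3 ± 8.31 CPM, a log2 fold change of 10.63 (SE 1.88, edgeR adjusted p = 0.000115). On the other side, unbinned_00558 stood at 2136 ± 1144 against 612550 ± 499120 CPM (log2 -8.16, SE 2.13, edgeR adjusted p = 0.00332). The gene unbinned_05440 stood at 1452 ± 590 against 556700 ± 473090 CPM (log2 -8.58, SE 2.16, edgeR adjusted p = 0.00241). Both are among the 4 features that lead outside the bins in SUC_73 b. These 4 took 74.3, 80.3 and 1.92% of annotated counts in SUC_73 a, b and c, and whether they are residual ribosomal RNA was not tested. The TMM factors of SUC_73 a, b and c were 0.456, 0.277 and 0.0516, which raises the CPM of these libraries. In these 4 genes the CPM of the 3 libraries of one carbon source all lay above the 3 of the other, as the naming rule required. For unbinned_05440 this rested on the TMM factors. It had 12183 of 5442401 annotated counts in SUC_73 c, a smaller fraction than the 8889 of 3181332 in TBZ_73 b.

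Of all tested genes, 7338 passed at 73 h, 5072 higher and 2266 lower, and CPM did not overlap for 11553 genes (50.2%, against 10% by chance). Without SUC_73 a the count was 2900. The median log2 fold change of all genes was 1.93 with TMM, 2.06 with RLE factors, 2.91 for genes of bins only and 4.71 with library totals only, when 15329 genes passed, so changes at 73 h are relative to a shifted centre. Bin_7C_Shinella and Bin_15D_Sphingopyxis turned with it. They had 541 and 240 lower genes with TMM, but with library totals only 784 Shinella and 51 Sphingopyxis genes were higher. Of the 19 genomes, 9 were higher and 4 lower in share on thiabendazole, and of binned counts 5 were higher and 9 lower. Among the calls in annotated counts, that of Bin_76_Unknown was lost in all 6 fits that left out 1 library, that of Tardiphaga in 4 and that of Bin_50_Bosea in 3.

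At 109 h, Sphingomonas genes were again the bulk of those higher on thiabendazole, with 2154 of 2654 higher (79.6% of the higher genes). Scaled within the genome, only 16 were higher and 3 lower (edgeR), so nearly all of these calls were not made once the shift of the whole genome was removed. SUC_109 a, b and c held only 19597, 10164 and 18892 Sphingomonas counts. In simulated data this fit recovered 45.5% of 16-fold changes at 109 h and 72.7% at 57 h. Fewer calls at 109 h than at 57 h thus need not mean fewer changes. The Sphingomonas share was 13.6% ± 11.8 against 0.472% ± 0.122 of annotated counts (n = 3 each), a log2 difference of 4.84 (SE 1.19, edgeR adjusted p = 0.00134). Novosphingobium took 0.278% ± 0.290 against 9.68% ± 2.31, a log2 difference of -5.12 (SE 1.32, edgeR adjusted p = 0.00171), and 1249 of its genes were lower. Bin_14H_Cupriavidus took 0.00867% ± 0.00252 against 1.08% ± 0.403 (log2 -6.96, SE 1.37, edgeR adjusted p = 0.000119), and all 356 of its tested genes were lower, as were all 54 of Bin_32A_Flavobacterium. With RLE factors, library totals only, genes of bins only or without the 5 libraries, at least 354 of the Cupriavidus genes and all 54 Flavobacterium genes were again lower. However, only 356 of 5654 Cupriavidus and 54 of 3267 Flavobacterium features passed the low-count filter. In the groups other than SUC_109 these genomes averaged at most 0.0259% and 0.00815%, so their genes passed the filter mainly through SUC_109. That all were lower was thus largely set by the filter, and these alternatives kept the same filter.

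Bin_93_NovosphingSphingom, a bin of 7 features, took 0.144% ± 0.178 against 19.6% ± 8.96 of annotated counts at 109 h (log2 -7.09, SE 2.05, edgeR adjusted p = 0.00986). This call was lost without TBZ_109 a (edgeR adjusted p = 0.123, and 0.000306 at the lowest of the fits that left out 1 library). Shinella had 880 lower genes of 2924, but its share, 3.02% ± 2.57 against 11.95% ± 2.12, did not pass (log2 -1.98, edgeR adjusted p = 0.205), and with library totals only 51 of its genes were lower. Bin_9B_Tardiphaga took 10.03% ± 8.44 against 6.24% ± 1.40, which did not pass (log2 0.686, edgeR adjusted p = 0.718). Of its 3866 genes, 56 were lower and 3 higher. With RLE factors this turned, to 602 higher and 4 lower.

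The gene unbinned_02411 stood at 53183 ± 76061 CPM on thiabendazole at 109 h against 529 ± 615 on succinate (log2 6.65, SE 1.78, edgeR adjusted p = 0.00485). The mean was carried by TBZ_109 b, one of the 5 libraries, at 140970 CPM against 11549 and 7027 in TBZ_109 a and c. Without it the log2 fold change was 4.74, and the call was kept in each fit that left out 1 library (edgeR adjusted p from 0.00311 to 0.0371). Bin_3X21F_Sphingomonas_00845bS stood at 14148 ± 7552 against 764 ± 398 CPM (log2 4.21, SE 1.61, edgeR adjusted p = 0.0467). Among the lower genes, Bin_93_NovosphingSphingom_00003 stood at 250 ± 295 against 80866 ± 52131 CPM (log2 -8.33, SE 2.13, edgeR adjusted p = 0.00332). Bin_5A_Novosphingobium_02682bS stood at 42.2 ± 26.0 against 33830 ± 20118 CPM (log2 -9.64, SE 2.26, edgeR adjusted p = 0.00149). All 3 libraries of one carbon source lay above all 3 of the other in each of these genes, as the naming rule required. The call of Sphingomonas_00845bS was lost under 8 of 18 alternatives (adjusted p from 0.000159 to 0.93).

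Of all tested genes, 5985 passed at 109 h, 2705 higher and 3280 lower, and CPM did not overlap for 9291 genes (40.4%, against 10% by chance). The balance depended on the scaling, since with RLE factors 3887 were higher and 1452 lower, and the median log2 fold change of all genes was 0.56 instead of -0.45. More genes were also higher than lower with DESeq2 (4343 and 1221), library totals only (2450 and 1552), genes of bins only (2539 and 1813) and the compared groups only (3076 and 2317). The same held without the 5 libraries (5375 and 3349) and without TBZ_109 b (4979 and 1938), TBZ_109 c (2633 and 1832) or SUC_109 c (2201 and 2107). Without TBZ_109 a the count was 3720. Of the 19 genomes, 2 were higher and 5 lower in share on thiabendazole, and the numbers were again 2 and 5 for binned counts. Of the 2 higher, Sphingomonas kept its call in each fit that left out 1 library, but Bin_76_Unknown did not. It took 0.397% ± 0.532 against 0.0408% ± 0.0510, with TBZ_109 c, at 0.00693%, below all SUC_109 libraries (log2 3.28, edgeR adjusted p = 0.037, exact permutation p = 0.5), and without TBZ_109 b the log2 difference was 1.21 (edgeR adjusted p = 0.498). This call was also lost without SUC_109 b or c, without the 5 libraries, with RLE factors over genomes and without the 20 most abundant features.

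**Figure D2:**
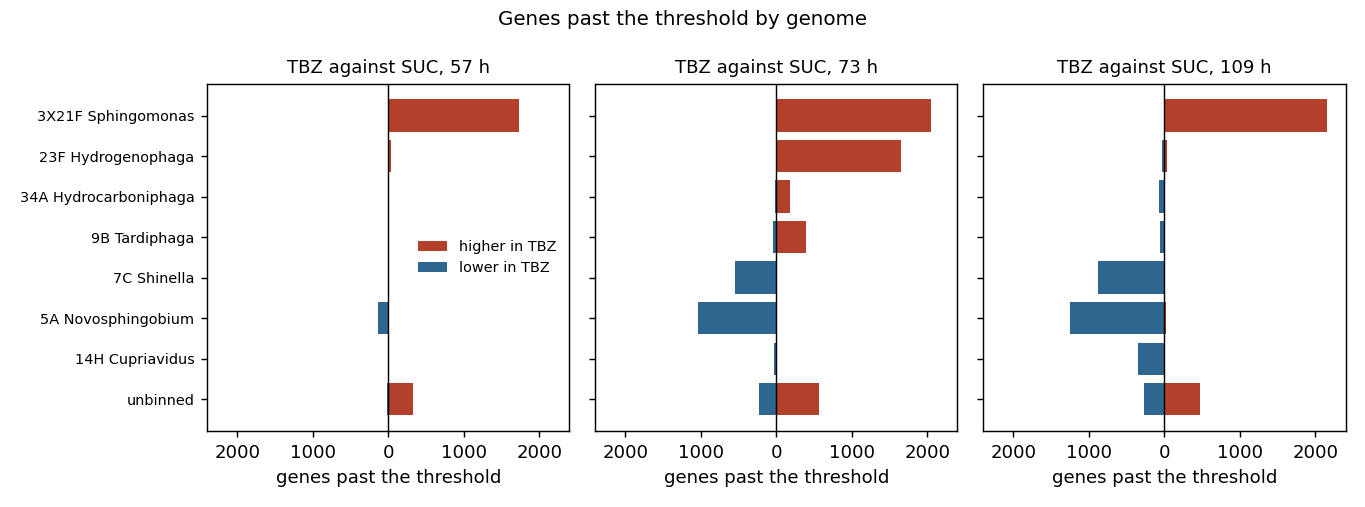
Numbers of genes higher (to the right) and lower (to the left) on thiabendazole than on succinate at 57, 73 and 109 h (edgeR, adjusted p under 0.05, TMM). Only some of the genomes are shown, with the features outside the bins. Sphingomonas had 1738, 2055 and 2154 higher genes at the 3 times. The lower calls of Shinella at 73 h turned to higher ones with library totals only, and the Tardiphaga calls at 109 h turned with RLE factors.

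**Figure D3:**
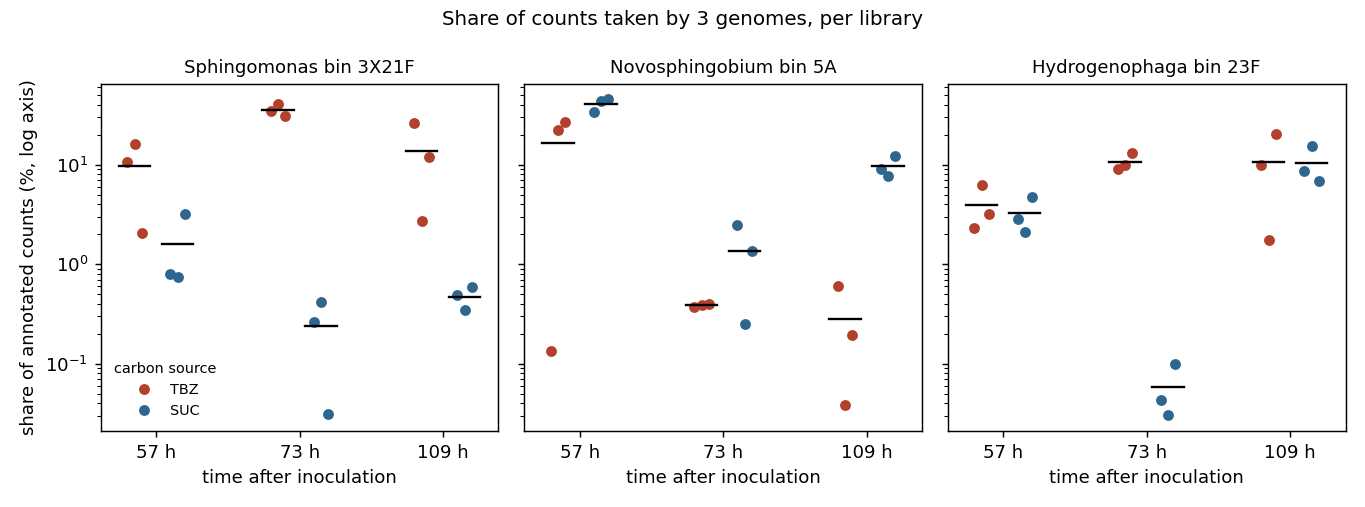
Share of annotated counts (%, log axis) of 3 genomes in each library by carbon source and time, each point 1 library and each black bar the mean of 3. Sphingomonas averaged 9.67, 35.5 and 13.6% on thiabendazole at 57, 73 and 109 h and 1.58, 0.238 and 0.472% on succinate.

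On thiabendazole between 57 and 73 h, Novosphingobium fell from 16.4% ± 14.3 to 0.385% ± 0.0168 of annotated counts (n = 3 each), a log2 change of -5.42 (SE 1.33, edgeR adjusted p = 0.00205). Cupriavidus fell too (log2 -5.89, edgeR adjusted p = 0.00144), and 5 of the 19 genomes passed, all lower at 73 h. These falls were not in all replicates. TBZ_57 a, one of the 5 libraries over 75% outside the bins, held 0.135% Novosphingobium (95% interval 0.129 to 0.141), below the 0.368 to 0.401% of the TBZ_73 libraries, while TBZ_57 b and c held 22.0 and 27.1%. It held no Cupriavidus count, which allows up to 0.00021%, below the 0.000261 to 0.00044% of TBZ_73. The exact permutation p of these 2 shares was 0.4 and 1. Of the genes, 1979 of Novosphingobium and 351 of Shinella were lower at 73 h, and Sphingomonas had 218 higher and 60 lower. The Sphingomonas share, at 9.67% ± 7.18 and 35.5% ± 5.05, did not differ past the test (log2 1.87, SE 1.05, edgeR adjusted p = 0.23). In all 3209 genes passed, 328 higher and 2881 lower. The count was 1812 without TBZ_57 c, 2052 without TBZ_73 a, 1651 without TBZ_73 c, 797 with library totals only, 2036 for genes of bins only, 1998 with DESeq2 and 793 with scaling within each genome, and with library totals only 10 Shinella genes were lower.

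On thiabendazole between 73 and 109 h, 1534 Sphingomonas genes and 580 genes of Bin_23F_Hydrogenophaga were lower at 109 h, against 1 and 18 higher. The share of this Hydrogenophaga did not differ past the test (edgeR adjusted p = 0.999), and with library totals only 5 of its genes were lower and 7 higher. Hydrocarboniphaga had 199 higher and 35 lower. Of the genome shares, that of Cupriavidus rose from 0.000374% ± 9.8e-05 to 0.00867% ± 0.00252 of annotated counts (n = 3 each, log2 4.52, edgeR adjusted p = 0.0157). This genome, a trace at both times, was the only 1 of the 19 to pass. The Sphingomonas share, 35.5% ± 5.05 at 73 h and 13.6% ± 11.8 at 109 h (n = 3 each), did not (log2 -1.39, SE 1.03, edgeR adjusted p = 0.744). In all 3138 genes passed, 397 higher and 2741 lower. The balance depended on the libraries and the scaling, with 1749 higher and 2113 lower without the 5 libraries, 451 and 716 without TBZ_109 b, 36 and 36 with library totals only and 782 and 823 with scaling within each genome. The count was 72 with library totals only, with 17 lower Sphingomonas genes, 1605 with scaling within each genome, and 1392, 1167 and 1622 without TBZ_73 b, TBZ_109 b and TBZ_109 c.

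On succinate between 57 and 73 h, 9 of the 19 genomes passed the test of their share of annotated counts, all lower at 73 h, where features outside the bins took 93.6% ± 3.88. Novosphingobium fell from 41.0% ± 6.02 to 1.37% ± 1.12 (n = 3 each, log2 -4.91, edgeR adjusted p = 0.00142), but in binned counts its change, -1.06, did not pass (edgeR adjusted p = 0.304). Bin_23F_Hydrogenophaga fell from 3.24% ± 1.38 to 0.0581% ± 0.0374 (log2 -5.80, edgeR adjusted p = 7.09e-05), but in binned counts its change, -1.48, did not pass either (edgeR adjusted p = 0.196). Of binned counts, 6 genomes were higher at 73 h and 1 was lower. No count of Bin_93_NovosphingSphingom was found in SUC_73 a, b or c, which allows shares of up to 0.000212, 0.000209 and 5.51e-05%, against 20.9% ± 1.22 in SUC_57. Among the genes, 654 passed, 211 higher and 443 lower at 73 h, with 203 lower in Novosphingobium, 101 lower in this Hydrogenophaga and 109 higher in Bin_15D_Sphingopyxis. The share of this Sphingopyxis did not pass in annotated counts (log2 -0.71, edgeR adjusted p = 0.463) but did in binned counts (log2 2.84, edgeR adjusted p = 0.00374). The balance turned under several alternatives, to 369 higher and 107 lower with RLE factors, 580 and 368 with DESeq2, 218 and 174 with the fixed filter and 73 and 4 for the compared groups only. It also turned without SUC_57 b (18 and 10), SUC_73 a (51 and 42) or SUC_73 b (26 and 5). The count of all genes was 28 without SUC_57 b, 124 without SUC_57 c, 93, 31 and 2848 without SUC_73 a, b and c, 77 for the compared groups only, and 14242 with library totals only.

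On succinate between 73 and 109 h, 16 of the 19 genomes passed, 15 of them higher at 109 h. Bin_23F_Hydrogenophaga rose from 0.0581% ± 0.0374 to 10.3% ± 4.58 of annotated counts (n = 3 each, log2 7.48, edgeR adjusted p = 4.08e-06). Hydrocarboniphaga rose from 0.389% ± 0.118 to 26.3% ± 6.31 (log2 6.08, edgeR adjusted p = 1.9e-05). In binned counts these rises were smaller, 3.05 and 1.94 on the log2 scale (edgeR adjusted p = 0.00598 and 0.0217). Of binned counts, 7 genomes were higher and 4 lower. Of the genes, 608 of this Hydrogenophaga, 525 of Hydrocarboniphaga and 95 of Cupriavidus were higher at 109 h, and 412 of Novosphingobium were lower. The Novosphingobium share of annotated counts went the other way and rose from 1.37% ± 1.12 to 9.68% ± 2.31 (log2 2.82, edgeR adjusted p = 0.028), while in binned counts its change, -1.15, did not pass (edgeR adjusted p = 0.261). With library totals only, 646 of its genes were higher and 30 lower, so the direction depended on the scaling. In all 2311 genes passed, 1612 higher and 699 lower, but with RLE factors 521 were higher and 1289 lower, with DESeq2 848 and 1693, and with voom 2512 and 3362. The count was 325, 1064 and 3616 without SUC_73 a, b and c, 1262, 1107 and 1324 without SUC_109 a, b and c, and 15940 with library totals only.

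The carbon source difference itself changed from 57 to 73 h in 743 genes, toward thiabendazole in 373 and toward succinate in 370. Bin_23F_Hydrogenophaga had 159, Sphingomonas 103 and Tardiphaga 65 genes whose difference moved toward thiabendazole. Shinella had 113, Novosphingobium 92 and Bin_15D_Sphingopyxis 67 that moved toward succinate. With library totals only, 344 Shinella and 152 Novosphingobium genes moved toward thiabendazole instead. The Sphingomonas share difference moved by 4.61 on the log2 scale (edgeR adjusted p = 0.00785), but by -0.05 in binned counts (edgeR adjusted p = 0.969). The number of genes was 1603, 238 and 178 without TBZ_57 a, b and c, 385 and 65 without SUC_57 b and c, 87, 104 and 211 without TBZ_73 a, b and c, and 42, 299 and 2434 without SUC_73 a, b and c. It was 368 with RLE factors and 11364 with library totals only. The even balance did not hold, with 89 toward thiabendazole and 279 toward succinate with RLE factors, 50 and 220 for the compared groups only, 11268 and 96 with library totals only, 1672 and 325 for genes of bins only, and 1728 and 706 without SUC_73 c.

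From 73 to 109 h the carbon source difference changed in 1246 genes, toward thiabendazole in 94 and toward succinate in 1152. Bin_23F_Hydrogenophaga held 854 of those that moved toward succinate, Commonadaceae 81, Tardiphaga 58 and Hydrocarboniphaga 49. With RLE factors 46 Hydrogenophaga genes did so. The share difference of this Hydrogenophaga moved by -7.48 in annotated counts (edgeR adjusted p = 7.65e-05) but by -2.95 in binned counts, which did not pass (edgeR adjusted p = 0.0539). The Sphingomonas share difference, at -2.38, did not change past the test (edgeR adjusted p = 0.144). The number of genes was 696, 613 and 784 without TBZ_73 a, b and c, 70 and 121 without SUC_73 a and b, 599 without TBZ_109 a, and 663 and 406 without SUC_109 a and b. It was 161 with RLE factors and 9049 with library totals only. The balance turned with RLE factors, to 93 toward thiabendazole and 68 toward succinate, and without SUC_73 a, to 42 and 28, and it was 57 and 64 without SUC_73 b.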

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

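The tests of the library make-up, of the Sphingomonas share and of TBZ_57 c were chosen only after the result was seen, including the bounds that decide them; the counts over other splits of the libraries were planned.

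The carbon source difference differed between 57 and 73 h in 743 genes and in 12 of the 19 genome shares (9 toward thiabendazole, 3 toward succinate), by edgeR's test of the difference itself. In binned counts 10 genomes passed, 2 toward thiabendazole and 8 toward succinate. It differed between 73 and 109 h in 1246 genes and in 9 genome shares (1 and 8), and in binned counts in 5 (3 and 2). Both involve SUC_73, and the gene counts were 42 and 70 without SUC_73 a. For each, 40 of 200 possible splits within the times were drawn, and 8 of the 40, the real one included, gave as many genes, with 7379 and 8575 as the highest others, so chance is not excluded by this count. The 7 others as large left the carbon source labels of one time whole and so carried that time's source difference, which is a structure of the samples, and the highest count of a split that left neither time whole was 0.

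Contigs without annotated features, which the comparisons do not use, took up to 55.8% of a library's counts (SUC_73 c), and 55.6% in TBZ_109 b and 49.2% in TBZ_57 a, against 0.308% in TBZ_109 c.

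Features outside the genomes took over 75% of the annotated counts in 5 libraries, and the tables argue against a single source of that RNA. The 4 features that lead outside the bins in TBZ_109 b took 84.3% of the outside-bin counts in TBZ_57 a and 96.6% in SUC_73 c, but only 0.0105% in SUC_73 a and 0.0034% in SUC_73 b, where 4 other features took 83.3% and 84.6%. A shallow library is excluded as a common cause, since 2 of them, SUC_73 c and TBZ_109 b, lie above the median total count of the 18, but it stays open for the other 3, which had the lowest total counts of all. Carbon source and time alone do not account for the shares over 75% in TBZ_57 a and TBZ_109 b, whose group mates reached at most 35.6% and 20.4%. Whether carbon source and time raised these shares in part cannot be decided from 3 libraries per group. For the high shares of the 3 in SUC_73, carbon source and time cannot be told apart from a technical source, since all 3 libraries of that group are among the 5. The features behind these shares differed within SUC_73, however. The 4 features leading in TBZ_109 b took 93.3% of annotated counts in SUC_73 c, against 0.00938% and 0.0032% in SUC_73 a and b. This argues against carbon source and time as the source of the RNA of these 4 features in SUC_73 c.

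On average, Sphingomonas took more of the counts on thiabendazole than on succinate, though at 57 h the test of its share of annotated counts did not pass. Dilution by outside-bin counts does not account for all of it, since in binned counts the lowest log2 difference over the 3 times was 3.75. That value was of 73 h, where the difference in annotated counts was 7.22, so dilution may account for part of it there. At 57 and 109 h the differences were larger in binned counts (3.80 and 5.48) than in annotated counts (2.61 and 4.84). A few very abundant genes do not account for all of the Sphingomonas difference either, since without the 20 most abundant features the lowest was 3.52. The carbon source itself stays open as the candidate explanation, because every thiabendazole library lay above every succinate library at only 2 of the 3 times, and at 57 h TBZ_57 c (3.17% of binned counts) lay below SUC_57 c (3.41%). This overlap had been seen when that bound was set.

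TBZ_57 c resembled the succinate libraries of its time, with a mean r of log CPM across genes of 0.784 with SUC_57 and 0.534 with the other TBZ_57 libraries. A swap with a succinate library of 57 h is excluded, since each SUC_57 library correlated better with the other SUC_57 libraries than with TBZ_57 a and b, by at least 0.413. A wrong label of TBZ_57 c is argued against by the profile of its Sphingomonas genes, whose r was 0.817 with TBZ_57 and 0.450 with SUC_57, a lead of 0.367. A mixture with RNA of succinate libraries of 57 h may account for the resemblance and stays open, since 3 of 19 genomes lay outside the range of the other 5 libraries, against 6.33 by chance. No biological explanation was tested for this library.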

How the results depend on the processing

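The fits without the 5 libraries over 75% outside the bins, those of bins only, the shares of binned counts and every within-Sphingomonas value were chosen only after the result was seen. The source comparisons at 57, 73 and 109 h first passed 2291, 7338 and 5985 genes, the thiabendazole times 3209 (73 against 57 h) and 3138 (109 against 73 h), the succinate times 654 and 2311, and the interactions 743 and 1246. Of the gene counts, 80 moved by more than 1.5 times under an alternative and 95 did not, and of 200 values of named genes 34 no longer passed, 166 kept their call and none reversed. Among genome share values, 563 stayed on their side of the threshold, 54 of them with the other sign, 28 no longer passed, 8 came to pass and 9 reversed. The gene list alternatives and the one without ribosomal RNA features were not run, and without the 5 libraries no value involving SUC_73 exists. The simulated 2-fold changes were not recovered at any time in the 23006 genes. Depth and spread were not varied there, so what limited the recovery was not tested. Unless construction shows it, the cause of a change was not tested.

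With RLE factors the interactions gave 368 and 161 genes, and 2289 of 2291, 7156 of 7338 and 4157 of 5985 calls were kept. At 109 h 3887 were higher and 1452 lower, and at 73 to 109 h on succinate 521 and 1289. With library totals only, which apply no composition factor, the counts were 1384 and 15329 at 57 and 73 h, 797 and 72 on thiabendazole, 14242 and 15940 on succinate, and 11364 and 9049 for the interactions. Scaling within each genome, which removes shifts of whole genomes and tests fewer genes, gave 491, 1208 and 352, then 793 and 1605, 244 and 1244, and 137 and 343. Without a filter succinate 73 against 57 h gave 1059, and the interactions 335 and 794. The fixed filter, which kept 24733 genes against 23006 in the main fit and so was not stricter, gave 392 for succinate 73 against 57 h. DESeq2 gave 1998 for thiabendazole 73 against 57 h and 1659 for the first interaction. Voom gave 2311 and 5874 on succinate. The compared groups alone gave 77 and 4060 on succinate, and 270 and 1906 for the interactions. Against a fold of 1.5, succinate 73 against 57 h gave 274 and the first interaction 440. Genes of bins only gave 2036 for thiabendazole 73 against 57 h, 3671 for succinate 109 against 73 h, and 1997 and 2259 for the interactions. Without the 5 libraries, 1605 passed at 57 h, 8724 at 109 h, and 4046 and 3862 on thiabendazole.

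The labels do not say whether the letters a, b and c pair the samples, and the main fits did not pair them. Not every same-letter correlation of deviations was over 0.1, which cannot show that pairing is absent. These ran from -0.396 to 0.0395 at 57 h, -0.0138 to 0.0389 at 73 h and -0.0707 to 0.0323 at 109 h, 0.0576 to 0.335 and 0.00777 to 0.231 over time on thiabendazole, and -0.0776 to 0.136 and -0.0640 to -0.0312 on succinate. As a hint from the data, all 3 libraries correlated best with their own letter for thiabendazole 73 against 57 h, and for no other comparison did all 3. This hint was picked from all the comparisons, and how often it arises without pairing was not tested. Of the 3 correlations for thiabendazole 73 against 57 h, 2 were over 0.1, so pairing over these times stays open. With a replicate block the counts were 2006, 7152 and 6178 by source, 3134 and 2972 on thiabendazole, 302 and 1886 on succinate, and 480 and 859 for the interactions. A replicate block within carbon source gave 403 and 825 for these.

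At 73 h RLE factors over genomes reversed the shares of Sphingopyxis 15D (-1.56), Agromyces (-2.63), Shinella (-1.60) and Tardiphaga (-0.029). Binned counts reversed the same 4 genomes (-2.23, -3.25, -2.28 and -0.63), and leaving out the 20 most abundant features reversed Agromyces (-1.78). Of these only Tardiphaga had passed. At 57 h, 1 genome share passed in binned counts and 1 without the 20 features, in both Sphingomonas (3.80 and 3.52). For Sphingomonas genes scaled within the genome, first 415 at 57 h and 19 at 109 h, genome totals only gave 11 at 109 h, and a separate fit of that genome 728 and 9.

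Leaving out 1 library gave 1418 to 3365 genes at 57 h (1418 without TBZ_57 b), 2900 to 8080 at 73 h (2900 without SUC_73 a) and 3720 to 6917 at 109 h (3720 without TBZ_109 a). On thiabendazole it gave 1651 to 3823 and 1167 to 3156, on succinate 28 to 2848 and 325 to 3616, and for the interactions 42 to 2434 and 70 to 1678, and the libraries that moved these counts are named with the comparisons. Genome shares passed for 10 to 11 genomes at 73 h and 6 to 7 at 109 h, and at 57 h for 0 in every fit (edgeR, 1 at unadjusted p under 0.05 with all libraries). Their Sphingomonas log2 difference ran from 2.01 to 3.64 at 57 h, 6.70 to 7.91 at 73 h and 3.94 to 5.33 at 109 h. Within Sphingomonas it was 189 to 463 at 57 h (218 without TBZ_57 b, 189 without SUC_57 c) and 2 to 18 at 109 h (10 without TBZ_109 a or b, and 6, 2 and 3 without SUC_109 a, b and c).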

Other observations

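The use of scaling within genomes as a result of its own, the choice of the 5 gene sets and the test for runs of feature numbers were chosen only after the result was seen; the scaling as an alternative and the counts over other splits of the report's comparisons were planned.

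Within Bin_3X21F_Sphingomonas, scaled to its own counts, 415 of 2654 genes differed between thiabendazole and succinate at 57 h, 310 higher and 105 lower (edgeR). At 109 h 19 differed, 16 higher and 3 lower, but leaving out 1 library gave 2 to 18, with no higher gene without SUC_109 b or c. The genome held 10164 to 19597 counts in the SUC_109 libraries, against 24046 to 161273 in SUC_57, so fewer calls at 109 h need not mean fewer differences. None of the 310 was also called higher at 109 h (1.87 expected for independent lists; edgeR, with 16 higher calls there and 277 genes at an unadjusted p under 0.05), which rests on these few calls. Of the 105 lower genes, 3 were also called lower and 2 higher at 109 h. Over all 2654 genes, the test of the difference between the 2 times itself passed for 17 with a lower and 85 with a higher log2 fold change at 109 h. It passed for 16 of the 310, whose log2 fold change was lower at 109 h (median over the 310 3.92 at 57 h and 0.58 at 109 h). Of the 105 it passed for 53, whose log2 fold change was higher there (median over the 105 -2.95 at 57 h and 0.91 at 109 h). Both sets were chosen for their difference at 57 h, which favours a weaker one at 109 h. At 57 h the count was 218 without TBZ_57 b and 189 without SUC_57 c. Within other genomes at 109 h, 106 Tardiphaga genes were lower on thiabendazole, 47 genes of Bin_23F_Hydrogenophaga were higher and 8 lower, and 81 Novosphingobium genes were higher and 37 lower. Novosphingobium took only 0.0387 to 0.601% of annotated counts in the TBZ_109 libraries, against 7.68 to 12.2% in SUC_109. Its calls thus rest on few counts in TBZ_109, and whether reads shared with related genomes add to these was not tested.

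The genes called within genomes may lie in transcribed blocks, which was tested by counting pairs with consecutive feature numbers against 10000 random sets of tested genes of the same genome, matched on mean count in 10 classes. The 310 Sphingomonas genes formed 125 such pairs (random median 42), and the 105 lower ones 24 (4). The 106 lower Tardiphaga genes formed 43 (4), the 47 higher Hydrogenophaga genes 34 (1) and the 81 higher Novosphingobium genes 30 (2). In each of the 5 sets the permutation p was 1e-04, the smallest these draws can give, also after adjustment over the 5. The files do not say that consecutive numbers are neighbours on a contig, so this remains a hypothesis.

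The longest run in Sphingomonas, numbers 121 to 141 (21 genes, chosen after their values were seen), took 1.49% ± 0.538 of that genome's counts in TBZ_57 and 0.0179% ± 0.00950 in SUC_57 (SD, n = 3 each; 3 to 20 counts per SUC_57 library). Its mean share was 0.0460% in TBZ_73 and 0.0160% in TBZ_109, below that of TBZ_57, and it was 0.0335% in SUC_109 (4 to 6 counts per library). In Tardiphaga, numbers 2530 to 2556 (27 genes) took 0.442% ± 0.0491 in TBZ_109 and 2.62% ± 1.35 in SUC_109. Its means lay the other way before, at 1.36% in TBZ_57 against 0.997% in SUC_57, and 1.88% in TBZ_73 against 0.759% in SUC_73 (61 to 114 counts per SUC_73 library). In Bin_23F_Hydrogenophaga, numbers 2528 to 2550 (23 genes) took 0.753% ± 0.200 and 0.0669% ± 0.0502. In Novosphingobium, numbers 249 to 256 (8 genes) took 2.21% ± 1.58 in TBZ_109 and 0.00690% ± 0.00240 in SUC_109. This rests on 49 to 324 counts per TBZ_109 library and 20 to 22 per SUC_109 library.

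With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave as many genes in each source and time comparison. The real counts and the highest of the other splits were 2291 and 1109 at 57 h, 7338 and 0 at 73 h, 5985 and 0 at 109 h, 3209 and 1862 for thiabendazole 73 against 57 h, 3138 and 0 for 109 against 73 h, 654 and 71 for succinate 73 against 57 h, and 2311 and 121 for 109 against 73 h. The split with 1109 set TBZ_57 a, TBZ_57 b and SUC_57 c against the rest, and that with 1862 set TBZ_57 a, TBZ_73 a and TBZ_73 c against the rest. Genome shares gave 13 against 0 at 73 h and 7 against 1 at 109 h, and at 57 h 0 against 1, so that all 10 splits gave as many. The within-Sphingomonas counts were 415 against 0 and 19 against 0.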
